A study of Mus musculus with 6 samples.

How the data were processed

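The series held 6 libraries of mouse liver polyadenylated RNA, 3 control and 3 Mst1/2 liver-dKO, and all 6 deposited files were used. Read alignment, counting and the conversion to RPKM were done by the authors before the files were deposited. The genome build was mm9 per the submitters' processing notes, while the aligner, the counting tool and the gene annotation were not given in the sources used here. That the values are RPKM was inferred from the values themselves, because low values among 3973 symbols with a single annotated transcript lay near whole multiples of 1 read. The fit used 282 to 446 such values per library, of which 72.1% to 78.3% lay within 0.15 of a whole read. Evenly spread values would give 30% at a fixed spacing. The spacing was chosen to fit these same values best, which raises the share expected by chance above 30%, so the unit was not tested. It gave the estimated depths of 17.25 to 25.1 M reads. Each file listed 22068 symbols, of which 19771 matched a GENCODE M21 symbol and 21822 a GENCODE or RefSeq symbol or synonym, and 5161 were at 0 in all libraries. The mm9 genome was not used here, and the reference tables served only for symbols and transcript lengths. The symbol Mst1 in the files is that of macrophage stimulating 1, and the kinases were read from Stk4 and Stk3.

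The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The design had asked for a test on counts and had named limma-trend for the case of normalized values. As the files hold RPKM and not counts, the limma fit was used, and the minimum of 5 CPM for named genes was read as 5 RPKM. Values were taken as log2(RPKM + 1), genes with a mean of at least 1 RPKM were kept (11062), and limma 3.58.1 in R 4.3.3 was run with trend and robust empirical Bayes moderation, without a block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, again with a correlation estimated per list, and with fry. Depth and figures used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

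The 33 lists covered Hippo components, YAP and TAZ targets, Notch, Wnt and pericentral, periportal, biliary, hepatocyte and oncofetal genes, proliferation, stellate and matrix, macrophage, lymphocyte and neutrophil, endothelial, erythroid and pancreatic markers. They also covered bile acid, cholesterol, lipogenesis, fatty acid oxidation, drug-metabolising cytochromes, NRF2, acute phase, interferon, coagulation and complement, female-biased, male-biased and sex chromosome genes. The last were circadian, immediate early, mitochondrial, TGF-beta, p53 and endoplasmic reticulum stress genes. The sex chromosome list served as a check only. Pancreatic genes had 0 tested members, the mitochondrial genes were absent from the files, and the lymphocyte and neutrophil list had 4 tested members, so these were not tested as lists.

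Named genes were Stk3 and Stk4, the 8 largest called changes in each direction with a mean of at least 5 RPKM and no overlap of the groups, up to 3 called members with the smallest p per list, and a fixed set of marker genes. Alternatives were a pseudocount of 0.1, no filter, a filter of at least 1 RPKM in 3 libraries, no robust moderation, a replicate block, each library left out, an adjusted p under 0.01, a minimum fold of 1.5, removal of sex-biased, Cyp, Mup and Sult genes, 4 scalings and sample weights. The scalings, the 3-library filter and the sample weights were chosen after seeing the data. In a test of the fit on 10 simulated sets of 10548 genes with 200 changed genes and a coefficient of variation of 0.126, 54% of changes of 1.5-fold, 99.7% of 2-fold and 100% of 4-fold were recovered, and 6.1% of the calls were unchanged genes. The simulated genes varied independently with the same coefficient, and their changes went up and down alike. In the data most calls were increases and genes of many lists were correlated, so these rates need not hold there. Left out were coordinates, isoforms and reads, none of which the files hold.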

Results

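Transcript levels were measured by sequencing polyadenylated RNA from the liver of C57BL/6 mice aged 6 weeks. There were 3 libraries from control mice and 3 from mice labelled as a liver double knockout of Mst1 and Mst2 (dKO). Mst1 and Mst2, called Stk4 and Stk3 in mouse nomenclature, are kinases of the Hippo pathway, which restrains the transcriptional coactivators YAP and TAZ. By the labels, mice of both groups were null for Mst1 and carried a loxP-flanked Mst2. The groups differed in the albumin-Cre transgene, which expresses Cre recombinase in the liver. Which liver cells had recombined was not measured. The deposited values were read as RPKM for 22068 gene symbols, of which 11062 had a mean of at least 1 RPKM and were tested. RPKM summed to between 364571 and 368246 in the control libraries and to between 324034 and 352678 in the dKO libraries. Read totals were not in the files, and the spacing of low values gave estimates of 17.25 to 25.1 M reads in control and 21.1 to 24.35 M reads in dKO libraries. The labels number the replicates without saying that they came from separate animals, so p-values measure the spread between these samples, which may be technical. Group values are means ± SD (n = 3 libraries), and log2 changes are dKO minus control on the log2(RPKM + 1) scale, which understates the change of low genes.

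The comparison asked which transcripts differed between Mst1-null livers with and without Cre-driven deletion of Mst2. Stk3 measured 6.00, 5.42 and 5.20 RPKM in control replicates 1, 2 and 3 and 5.13, 4.25 and 5.32 RPKM in dKO replicates 1, 2 and 3. This was a log2 change of -0.15 ± 0.13 (SE) with a limma adjusted p of 0.424. Stk4 measured 5.50, 4.69 and 4.66 RPKM in the control and 5.84, 4.93 and 5.76 RPKM in the dKO libraries. Its log2 change was 0.13 ± 0.13 (SE) with a limma adjusted p of 0.487. The Stk4 log2 fold change turned negative with median-ratio scaling (-0.08), upper-quartile scaling (-0.08) and quantile normalization (-0.16). Stk3 passed the threshold with quantile normalization, where the Stk3 log2 fold change was -0.44 with a limma adjusted p of 0.0475 (range 0.0475 to 0.748 over the 17 alternatives that keep the threshold, which leave out an adjusted p under 0.01 and a minimum fold of 1.5). A value per gene does not resolve a deleted part of a gene, so these levels did not test the genotype labels.

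Of 11062 tested genes, 1965 were called higher and 240 lower in dKO liver. The higher calls took in 9 of 19 targets of YAP and TAZ, 13 of 14 cholangiocyte and progenitor markers and 5 of 11 fetal liver genes, and 1 target was called lower. Of 18 Wnt targets and pericentral hepatocyte genes 12 were called lower, as were 9 of 24 drug-metabolising cytochromes. Tested as lists with an estimated correlation, none of these groups passed (camera adjusted p from 0.243 to 0.527). Ctgf, which encodes connective tissue growth factor, a target of YAP, rose 5.93-fold, from 2.69 ± 1.01 to 15.9 ± 2.10 RPKM. Spp1, which encodes osteopontin, rose 16.0-fold, from 34.8 ± 25.9 to 556 ± 315 RPKM, and 28.1-fold without control replicate 3. Glul, the pericentral glutamine synthetase, fell to 0.273 of its control level, from 216 ± 15.4 to 58.8 ± 16.4 RPKM. Among called genes with a mean of at least 5 RPKM and no overlap between the groups, the 8 largest increases were Ptgds (a prostaglandin D synthase), Spink3 (a serine protease inhibitor), Cib3, Spp1, Mup20 (a major urinary protein of male liver), Gpc3 (a glypican of fetal liver), Sox4 (a transcription factor) and Lgals1 (galectin 1). Their log2 changes ran from 4.61 for Ptgds, which went from 4.33 ± 2.18 to 124 ± 28.9 RPKM, to 3.43 for Lgals1, whose dKO libraries held 25.7, 16.7 and 157 RPKM and whose log2 change was 2.47 without dKO replicate 3. The 8 largest decreases were the sulfotransferases Sult2a5, Sult2a3, Sult2a1 and Sult5a1, the cytochromes Cyp4a14 and Cyp3a16, Hamp2 (a hepcidin paralog) and Igfbp2 (an insulin-like growth factor binding protein). Their log2 changes ran from -3.50 for Sult2a5 to -2.45 for Sult5a1, and Igfbp2 went from 154 ± 38.9 to 27.8 ± 11.3 RPKM. Without dKO replicate 1 the log2 change was -4.43 for Sult2a5 and -3.02 for Sult5a1. Reads of the Sult2a, Cyp3a, Cyp4a, Mup and hepcidin genes can be shared with near-identical copies, so the values of single members are uncertain.

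With limma and Benjamini-Hochberg adjustment, 2205 genes passed an adjusted p of 0.05, 1965 higher and 240 lower in dKO, so that 89.1% of the calls were increases. After median-ratio scaling of the RPKM, chosen after seeing the data, 958 genes were higher and 536 lower (64.1% increases), and no gene was called in opposite directions. That scaling moved the median log2 change of the tested genes by 0.21, from 0.23 to 0.02. RPKM is relative to all reads, and the 20 most abundant genes of each library held 31.0% to 36.7% of the RPKM sum in control and 26.9% to 30.7% in dKO libraries. The groups did not overlap at 4986 tested genes (45.1%), and 10% would be reached by chance. With 1 library left out there were 755 to 1983 increases, with 755 without control replicate 1, 947 without control replicate 3, 1171 without dKO replicate 1 and 1050 without dKO replicate 3. Decreases numbered 90 to 241, with 90 and 116 without control replicates 1 and 3 and 155 and 127 without dKO replicates 2 and 3. Some of the genes just named lost their call when 1 library was left out, with limma adjusted p of up to 0.114. These losses came without each control replicate for Lgals1, Sult2a5, Sult2a1, Cyp4a14 and Cyp3a16, without control replicates 2 and 3 for Sult5a1, and without control replicate 1 for Hamp2. They also came without dKO replicate 1 for Lgals1, Cyp3a16 and Hamp2, without dKO replicate 2 for Sult2a5 and Sult5a1, and without dKO replicate 3 for Sult2a5, Sult2a1, Sult5a1 and Hamp2. Scaling to the sum without the top 20 genes ended the calls of Lgals1 and Sult2a1 (limma adjusted p = 0.0596 and 0.051). Sample weights ended those of Sult2a5 and Sult2a1 (0.0939 and 0.128), and Sult5a1 lost its call with a pseudocount of 0.1 and Hamp2 without a filter. Of 16 alternatives, 7 ended the call of Sult2a5 and 6 that of Sult5a1, not all of which are named here. The limma adjusted p over the alternatives reached 0.114 for Lgals1, 0.0939 for Sult2a5, 0.128 for Sult2a1, 0.164 for Sult5a1, 0.0776 for Cyp4a14, 0.103 for Cyp3a16 and 0.0849 for Hamp2. On the first principal component (67.3% of the variance) the dKO libraries lay at 20.3, 19.2 and 49.0 and the controls at -35.7, -27.5 and -25.5, so dKO replicate 3 stood apart from the other dKO libraries.

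**Figure D1:**
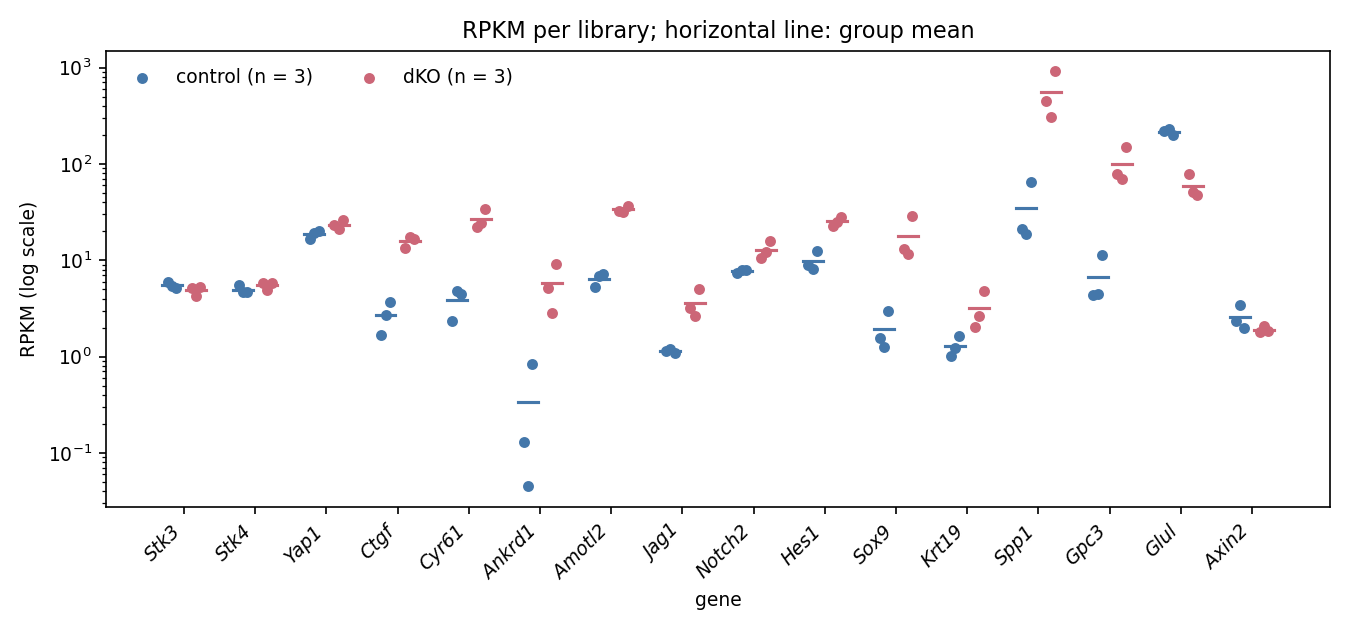
RPKM of 16 genes (log scale) in each of the 3 control (blue) and 3 dKO (red) libraries, with a horizontal line at the group mean. The groups overlap for Stk3, Stk4 and Axin2, while the dKO libraries of Amotl2 lie around 33.7 RPKM against 6.41 RPKM in controls and those of Glul around 58.8 RPKM against 216 RPKM.

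Of 33 gene lists fixed before the data were examined, 29 had at least 5 tested members, and camera, with a preset correlation of 0.01, placed 21 of them apart from the other genes, 9 up and 12 down. With a correlation estimated for each list, 0 lists passed at an adjusted p of 0.05 and 3 had an unadjusted p under 0.05, while fry, which tests each list against no change, called 12 lists in a direction and 26 in either direction. Each list is described by its members called over all genes tested, with the count adjusted over the list alone and the count after median-ratio scaling beside it. Of all 11062 tested genes, 1965 were called higher and 240 lower, so a list count near these shares is not particular to the list. Some genes stand on several lists and are counted in each, so the lists are not independent. Examples are Sox9 (Notch and biliary), Amotl2 (Hippo and YAP targets), Tgfb2 (YAP targets and TGF-beta) and Cyp2b9 (cytochromes and female-biased).

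Calls among Hippo pathway genes and targets of YAP and TAZ were mainly increases, as were 89.1% of all calls. Of 22 Hippo components, 9 rose and 0 fell (10 and 0 adjusted over the list alone, 7 and 1 after scaling), among them Amotl2, Amot and Wwc1, which encode scaffold proteins of the pathway. Amotl2 rose from 6.41 ± 0.99 to 33.7 ± 2.77 RPKM (limma adjusted p = 0.000364). Yap1, which encodes the coactivator itself, stood at 18.6 ± 1.91 RPKM in control and 23.5 ± 2.64 RPKM in dKO, with a limma adjusted p of 0.12. For the Hippo list camera gave an adjusted p of 0.023, with adjusted p = 0.59 with an estimated correlation, and without control replicate 2 it was 0.0677. Of 19 published YAP and TAZ targets, 9 rose and 1 fell (12 and 2 adjusted over the list alone, 7 and 1 after scaling), with 5 increases without control replicate 1 and 2 decreases without dKO replicate 2. Besides Ctgf, the matricellular protein gene Cyr61 rose with a log2 change of 2.54 ± 0.24 (SE). Ankrd1, a nuclear ankyrin repeat protein gene, rose 17.0-fold, from 0.338 ± 0.436 to 5.75 ± 3.23 RPKM, and 65.4-fold without control replicate 3. Nt5e, an ecto-nucleotidase gene, fell from 30.4 ± 3.53 to 14.1 ± 3.80 RPKM. For the targets camera gave an adjusted p of 0.0194, with adjusted p = 0.527 with an estimated correlation.

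Biliary markers were called higher in nearly every case and Notch genes in part. Of 12 Notch ligands, receptors and targets, 8 rose and 0 fell (9 and 0 adjusted over the list alone, 4 and 0 after scaling). The ligand gene Jag1 rose from 1.14 ± 0.06 to 3.63 ± 1.28 RPKM, the target Hes1 from 9.82 ± 2.22 to 25.4 ± 2.67 RPKM, and the receptor gene Notch2 from 7.77 ± 0.36 to 12.9 ± 2.70 RPKM. The call of Notch2 was lost after median-ratio scaling (limma adjusted p = 0.0621), upper-quartile scaling and quantile normalization and without control replicate 1 or 3, where limma adjusted p reached 0.0776 (range over 17 alternatives 0.00839 to 0.0776). Without control replicate 1 or 3, 4 Notch genes rose, and 5 did so without dKO replicate 2 or 3; the camera adjusted p was 0.0194, with adjusted p = 0.414 with an estimated correlation. Of 14 cholangiocyte and progenitor markers, 13 rose and 0 fell (14 and 0 adjusted over the list alone, 11 and 0 after scaling), with a median log2 change of 1.71 (1.44 without dKO replicate 3, which held the highest Spp1, Sox9 and Bicc1 values). Sox9, a transcription factor gene of cholangiocytes and progenitors, rose 9.17-fold to 17.7 ± 9.39 RPKM. Bicc1, an RNA-binding protein gene, rose 10.7-fold to 26.1 ± 10.2 RPKM (17.4-fold without control replicate 3), and Prom1, which encodes the progenitor surface protein CD133, rose 3.35-fold to 26.0 ± 6.34 RPKM. Krt19, a keratin of cholangiocytes, rose from 1.29 ± 0.32 to 3.18 ± 1.47 RPKM with a limma adjusted p of 0.0473. This call was lost after each of the 4 scalings (median-ratio 0.0861), without a filter, with sample weights and without any of 5 libraries, with limma adjusted p of up to 0.142 and dKO replicate 1 as the exception (range over 17 alternatives 0.0239 to 0.181). With camera the biliary list had an adjusted p of 7.3e-07, with adjusted p = 0.414 with an estimated correlation.

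Of 11 fetal liver and oncofetal genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone, 5 and 0 after scaling). Without control replicate 2, 1 fell. Gpc3 rose 14.9-fold to 99.5 ± 43.5 RPKM (22.5-fold without control replicate 3), Sox4 15.3-fold to 32.2 ± 14.5 RPKM (25.5-fold without control replicate 3) and Ly6d, a surface protein gene, 13.4-fold to 10.8 ± 5.27 RPKM. Afp, which encodes alpha-fetoprotein, stood at 1.44 ± 0.18 RPKM in control and 3.00 ± 2.10 RPKM in dKO, with 5.38 RPKM in dKO replicate 3 and a limma adjusted p of 0.213. With camera the fetal list had an adjusted p of 0.0345, with adjusted p = 0.52 with an estimated correlation, and it was 0.0934 without control replicate 2 and 0.0596 without dKO replicate 3. The list median of 1.43 was 0.35 without dKO replicate 3.

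Calls among Wnt targets and pericentral hepatocyte genes were decreases. Of 18 Wnt targets and pericentral genes, 0 rose and 12 fell (0 and 13 adjusted over the list alone, 0 and 12 after scaling), and 8 to 12 fell when 1 library was left out. Gulo, an enzyme gene of ascorbate synthesis, fell from 144 ± 5.96 to 57.3 ± 10.3 RPKM, Rhbg, an ammonium transporter gene, from 7.73 ± 1.14 to 3.33 ± 0.10 RPKM, and Glul as given above with a limma adjusted p of 0.00121. Axin2, a target of beta-catenin signalling, stood at 2.58 ± 0.75 and 1.91 ± 0.14 RPKM, with a limma adjusted p of 0.271 that was 0.047 under quantile normalization of the Axin2 log2 fold change (range over 17 alternatives 0.047 to 0.627). Tested by camera, the pericentral list had an adjusted p of 5.33e-19, with adjusted p = 0.243 with an estimated correlation. Of 17 periportal genes, 1 rose and 4 fell (3 and 7 adjusted over the list alone, 0 and 5 after scaling), among them Ass1, a urea cycle enzyme gene that fell from 240 ± 30.9 to 79.9 ± 23.9 RPKM, and Tat, a tyrosine aminotransferase gene that fell from 356 ± 46.1 to 148 ± 43.2 RPKM. Without control replicate 1 or 3, 2 periportal genes fell, and 3 rose without dKO replicate 3, 2 without control replicate 2 and 0 without any other library; the camera adjusted p was 1.17e-07, with adjusted p = 0.401 with an estimated correlation.

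Of 20 hepatocyte identity genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone, 0 and 3 after scaling). Alb, the albumin gene, stood at 43195 ± 6100 RPKM in control and 36501 ± 2121 RPKM in dKO, with a limma adjusted p of 0.527. The genes that fell were Hpd, a tyrosine breakdown enzyme gene, Serpina1c, an antitrypsin gene, and Ttr, the transthyretin gene, which went from 6223 ± 1055 to 2906 ± 1097 RPKM. Without control replicate 2 or dKO replicate 3, 1 hepatocyte gene rose. None of the 3 that fell kept its call without control replicate 1 or 3 or without dKO replicate 1 or 3, with limma adjusted p of up to 0.0682, 0.12 and 0.128, and quantile normalization or the lack of a filter ended all 3 calls. Ttr lost its call also after median-ratio scaling (0.059), upper-quartile scaling and without robust moderation (range over 17 alternatives 0.00365 to 0.308). With a replicate block 1 hepatocyte gene fell, and the calls of Serpina1c and Ttr were lost. Tested by camera, the hepatocyte list had an adjusted p of 0.000109, with adjusted p = 0.402 with an estimated correlation. Under quantile normalization the list test pointed up with a camera adjusted p of 0.853. Of 24 drug-metabolising cytochromes, 0 rose and 9 fell (0 and 10 adjusted over the list alone, 0 and 10 after scaling), including Cyp2c37 (229 ± 21.5 to 72.6 ± 29.1 RPKM) and Cyp2c29 (771 ± 131 to 250 ± 102 RPKM). Without control replicate 1, 4 cytochromes fell, and 5 fell without dKO replicate 2 or 3; the camera adjusted p was 6.67e-13, with adjusted p = 0.401 with an estimated correlation.

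Among 14 genes that are higher in female mouse liver, 0 rose and 6 fell (0 and 7 adjusted over the list alone, 0 and 7 after scaling), with a median log2 change of -1.68. Sult2a2 fell from 382 ± 99.9 to 102 ± 30.9 RPKM, and Acot3, an acyl-CoA thioesterase gene, from 16.0 ± 7.77 to 3.21 ± 0.81 RPKM. Without control replicate 3, 2 of these genes fell, and 3 fell without control replicate 1 or dKO replicate 3; the camera adjusted p was 3.57e-11, with adjusted p = 0.321 with an estimated correlation. Of 12 genes higher in male mouse liver, 2 rose and 0 fell (2 and 0 adjusted over the list alone, 1 and 0 after scaling), Mup20 (1.79 ± 0.23 to 41.0 ± 20.7 RPKM) and C6, a complement component gene. Of the male list, 1 gene rose without control replicate 1 or 3 and 3 without control replicate 2, and 1 fell without dKO replicate 1. The call of C6 was lost after median-ratio scaling (limma adjusted p = 0.0846), upper-quartile scaling and quantile normalization, without a filter and without control replicate 1 or 3 or dKO replicate 2 or 3, with limma adjusted p of up to 0.0983 (range over 16 alternatives 0.00482 to 0.117). The male list had a median log2 change of 0.33 (0.20 without control replicate 2, 0.08 without dKO replicate 2) but a camera direction of down, with a camera adjusted p of 0.434 and adjusted p = 0.745 with an estimated correlation. That direction was up after median-ratio scaling, upper-quartile scaling and quantile normalization and without dKO replicate 3 (camera adjusted p of 0.637 to 0.935). Xist, the RNA that silences an X chromosome in females, lay between 55.7 and 93.5 RPKM in all 6 libraries, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty did not exceed 0.027 RPKM in any, with Ddx3y listed at 0 throughout. Xist rose from 59.3 ± 5.04 to 84.5 ± 7.79 RPKM (limma adjusted p = 0.0407). This call was lost after median-ratio scaling (limma adjusted p = 0.215), upper-quartile scaling and quantile normalization, without a filter and with a replicate block. It was also lost without any library except control replicate 2, with limma adjusted p of up to 0.134 (range over 16 alternatives 0.00471 to 0.215).

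Markers of other liver cells were examined next. Of 22 stellate cell and matrix genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone, 2 and 0 after scaling), led by Rgs5, a pericyte gene, at 8.51 ± 1.61 and 22.7 ± 5.44 RPKM. The camera adjusted p of the stellate list was 0.0879, with adjusted p = 0.733 with an estimated correlation, and it was 0.012 after median-ratio scaling. With a replicate block it was 0.0184, and 8 stellate genes rose. Without control replicate 1 or 3, 1 stellate gene rose, 2 rose without control replicate 2 or dKO replicate 1, and 8 rose without dKO replicate 2. Leaving out dKO replicate 1, 2 or 3 brought camera adjusted p values of 0.024, 0.00544 and 0.334 for the stellate list, and leaving out control replicate 1, 2 or 3 brought 0.112, 0.201 and 0.0699. Of 15 macrophage markers, 3 rose and 0 fell (5 and 1 adjusted over the list alone, 2 and 1 after scaling), led by the Kupffer cell receptor gene Vsig4 at 14.5 ± 1.18 and 26.6 ± 5.02 RPKM. Macrophage markers had a camera adjusted p of 0.434, with adjusted p = 0.822 with an estimated correlation, and of 0.0479 in the up direction under quantile normalization. Without control replicate 2 the camera adjusted p was 0.00984 with 11 increases. This stood against 1 increase and 1 decrease without control replicate 3, where the direction was down. Of 19 endothelial markers, limma called 0 (0 adjusted over the list alone, 0 after scaling) and 2 had an unadjusted p under 0.05, with a median log2 change of 0.22 (0.14 without control replicate 3), a camera direction of down a camera adjusted p of 0.434 and adjusted p = 0.722 with an estimated correlation. With fry the endothelial adjusted p was 0.176, and leaving out control replicate 2 or dKO replicate 2 gave 1 increase. Of 5 red blood cell genes, limma called 0 (0 adjusted over the list alone) and 0 had an unadjusted p under 0.05. Their camera adjusted p was 0.00705 in the down direction, with adjusted p = 0.43 with an estimated correlation, 0.14 without control replicate 3 and 0.0529 after median-ratio scaling. Without control replicate 2, 2 red blood cell genes fell. Of lymphocyte and neutrophil markers, 4 were tested, limma called 0 and 1 had an unadjusted p under 0.05, while no pancreatic acinar gene reached the filter. Mitochondrial transcripts were absent from the files and were not analysed here.

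**Figure D2:**
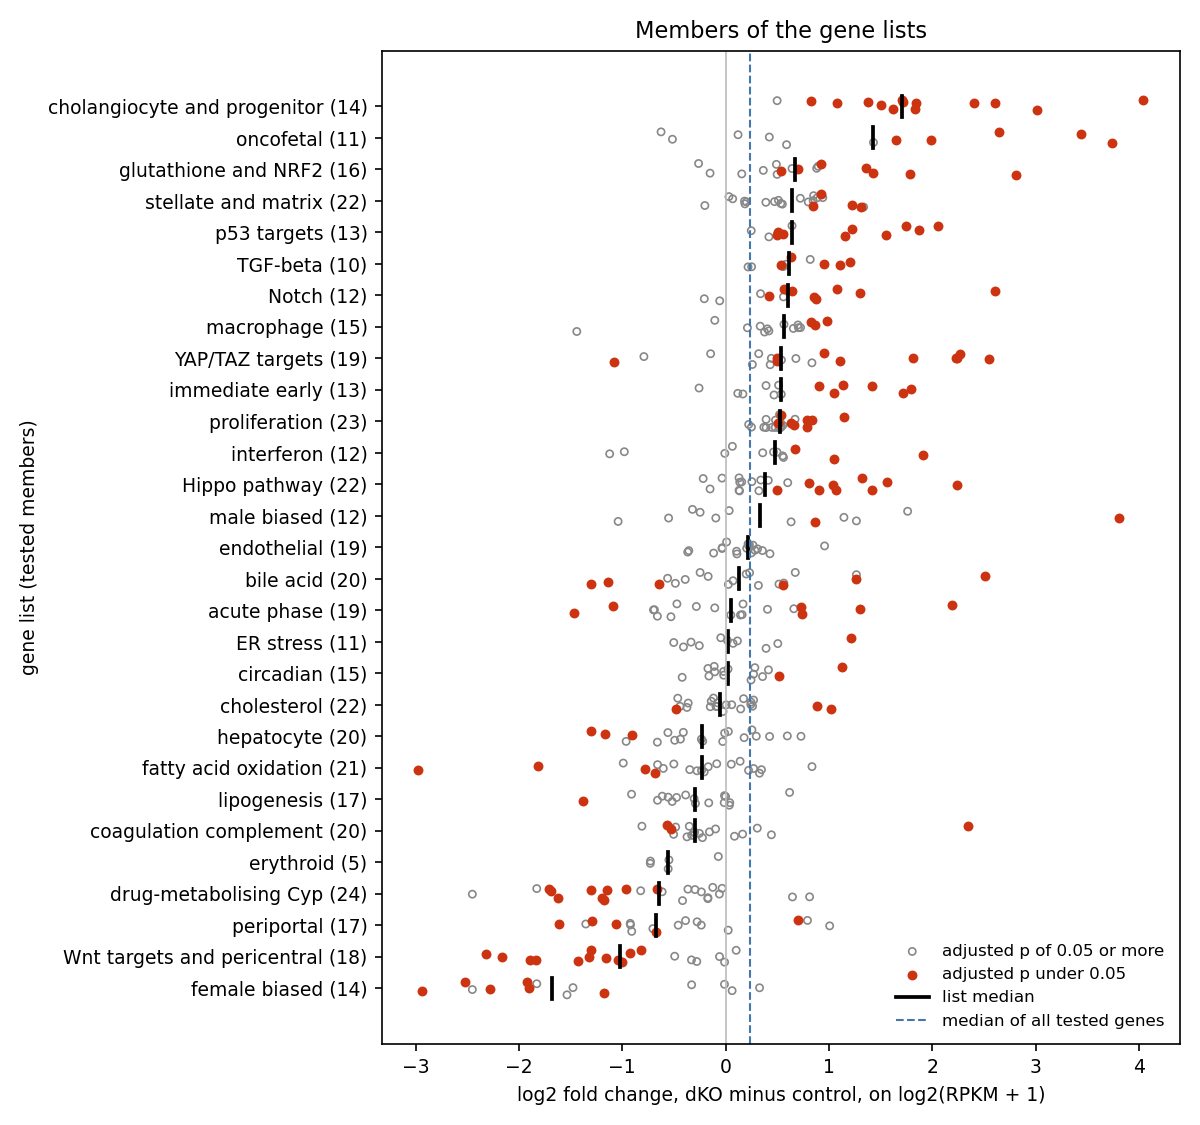
Log2 change, dKO minus control, of each tested member (points) of 29 gene lists, with red points for limma adjusted p under 0.05, a black bar for the list median and a dashed line for the median of all tested genes (0.23). Cholangiocyte and progenitor markers had the highest list median (1.71) and female-biased genes the lowest (-1.68), while the endothelial median (0.22) lay near that of all genes; median-ratio scaling lowers that of all genes by 0.21 and turns the endothelial median to -0.03.

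Most p53 targets and a smaller part of the cell cycle genes were called higher. Of 23 cell cycle and replication genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone, 3 and 0 after scaling). Ccnb2, which encodes cyclin B2, rose from 4.68 ± 0.32 to 11.7 ± 2.50 RPKM, and Mki67, which encodes the proliferation marker Ki-67, from 6.48 ± 1.10 to 11.8 ± 1.23 RPKM, a call lost for Mki67 after upper-quartile scaling, quantile normalization and median-ratio scaling (limma adjusted p = 0.0575, range over 17 alternatives 0.00224 to 0.0662). Without control replicate 2, 13 of these genes rose, and 5 rose without control replicate 1 or 3; the camera adjusted p was 0.001, with adjusted p = 0.414 with an estimated correlation. Of 13 p53 targets, 9 rose and 0 fell (12 and 0 adjusted over the list alone, 6 and 0 after scaling), and 5 rose without dKO replicate 3. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 9.78 ± 1.35 to 35.2 ± 4.75 RPKM, and Plk2, a polo-like kinase gene, from 3.40 ± 0.74 to 17.2 ± 2.75 RPKM. For the p53 list the camera adjusted p was 6.66e-05, with adjusted p = 0.401 with an estimated correlation. Of 10 TGF-beta genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone, 3 and 0 after scaling), including the ligand gene Tgfb2, which lost its call under quantile normalization (limma adjusted p = 0.065) and without control replicate 1 (0.0718, range over 17 alternatives 0.0032 to 0.0718). Without control replicate 1 or dKO replicate 3, 1 TGF-beta gene rose, 2 rose without control replicate 2, and 3 rose without control replicate 3 or dKO replicate 2. For TGF-beta genes camera gave an adjusted p of 0.0267, with adjusted p = 0.52 with an estimated correlation, and 0.0625 without control replicate 2. Of 13 immediate early and heat shock genes, which also respond to tissue handling, 6 rose and 0 fell (7 and 0 adjusted over the list alone, 5 and 0 after scaling), led by Jun at 6.06 ± 1.48 and 24.1 ± 9.30 RPKM. Their camera adjusted p was 0.0555, with adjusted p = 0.527 with an estimated correlation, 0.0165 after median-ratio scaling and 0.0184 with a replicate block. Each of the 3 fits without a control library left 3 of them higher, and their camera adjusted p was 0.0118, 0.201 and 0.0646 without control replicates 1, 2 and 3. Without dKO replicates 1, 2 and 3 it was 0.0209, 0.0429 and 0.0438.

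Bile acid and acute phase genes were called in both directions. Of 20 bile acid genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, 2 and 3 after scaling). The sterol 12-alpha-hydroxylase gene Cyp8b1 rose 5.06-fold, from 16.4 ± 12.9 to 83.0 ± 4.95 RPKM (9.27-fold without control replicate 3), the exporter gene Abcc3 rose 2.44-fold, and the uptake transporter gene Slc10a1 fell from 287 ± 23.8 to 121 ± 41.1 RPKM. Of 22 cholesterol genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, 1 and 1 after scaling). Of 17 lipogenesis genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone, 0 and 4 after scaling), and of 21 fatty acid oxidation genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone, 0 and 4 after scaling). Of 19 acute phase genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, 1 and 2 after scaling), led by Lcn2, which encodes lipocalin 2 and rose 5.29-fold to 90.1 ± 53.4 RPKM (3.49-fold without dKO replicate 3). Of 20 coagulation and complement genes, 1 rose and 2 fell (1 and 1 adjusted over the list alone, 1 and 3 after scaling), and the increase was C9, a component of the membrane attack complex, from 52.8 ± 8.15 to 272 ± 32.7 RPKM. The camera adjusted p for these lists, all in the down direction, was 0.0267 for bile acid, 0.0232 for cholesterol, 1.5e-07 for lipogenesis, 3.08e-06 for fatty acid oxidation, 0.0194 for acute phase and 7.05e-06 for coagulation and complement genes. In the same order, these lists had adjusted p = 0.499, 0.414, 0.321, 0.401, 0.414 and 0.401 with an estimated correlation. The bile acid and acute phase lists had medians above 0 (0.13 and 0.05) despite a test that pointed down. The acute phase median was below 0 without any library except dKO replicate 3 (-0.14 to -0.01), and the bile acid median was 0.21 without control replicate 2 and 0.07 without dKO replicate 3. After median-ratio scaling their camera adjusted p was 0.155 and 0.216. Under quantile normalization, camera adjusted p was 0.196 for cholesterol, 0.0649 for fatty acid oxidation and 0.574 for coagulation and complement genes. Fatty acid oxidation genes fell in numbers of 0, 1, 2 and 2 without control replicate 1, control replicate 3, dKO replicate 2 and dKO replicate 3. Lipogenesis counts moved as well, and 3 genes fell without control replicate 2 or dKO replicate 1 and 0 without control replicate 1. Without control replicate 2, 1 lipogenesis gene rose, and without control replicate 3, 1 fatty acid oxidation gene rose. Without dKO replicate 3, the camera adjusted p was 0.0991 for bile acid, 0.128 for cholesterol and 0.115 for acute phase genes. It was 0.0928 for bile acid and 0.0543 for cholesterol genes without control replicate 3, and 0.0884 for acute phase genes without control replicate 1. Acute phase increases numbered 1 without control replicate 3 or dKO replicate 3 and 2 without control replicate 1, dKO replicate 1 or dKO replicate 2. Acute phase decreases numbered 1 without control replicate 2 or 3 and 0 without control replicate 1 or any dKO replicate. Cholesterol decreases numbered 0 without control replicate 1 or 3 or dKO replicate 2 or 3. Coagulation and complement decreases numbered 1 without dKO replicate 2 and 0 without control replicate 1 or 3 or dKO replicate 1 or 3, and 2 genes of that list rose without control replicate 2.

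Of 16 glutathione and NRF2 target genes, 7 rose and 0 fell (11 and 0 adjusted over the list alone, 5 and 1 after scaling), led by Ephx1, an epoxide hydrolase gene, with a log2 change of 1.36 ± 0.18 (SE). Without control replicate 2, 11 of these genes rose, 3 rose without control replicate 1 or dKO replicate 1 or 3, and 2 rose without control replicate 3, where the camera adjusted p was 0.0587; with all libraries it was 0.0267, with adjusted p = 0.527 with an estimated correlation. Of 12 interferon response genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone, 3 and 0 after scaling), led by Ifit2 at 2.57 ± 0.71 and 12.3 ± 1.91 RPKM. The interferon list had a camera adjusted p of 0.508, with adjusted p = 0.839 with an estimated correlation. It had 7 increases and a camera adjusted p of 0.0236 without control replicate 2, and 1 increase without control replicate 1 or 3. The camera direction of the interferon list was down without control replicate 3 (camera adjusted p = 0.694). Of 15 circadian clock genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone, 1 and 0 after scaling), with 0 without control replicate 1 and 1 without control replicate 3 or dKO replicate 1, and their camera adjusted p was 0.335, with adjusted p = 0.52 with an estimated correlation. Of 11 endoplasmic reticulum stress genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, 1 and 0 after scaling), Trib3, a pseudokinase gene, at 3.18 ± 1.05 and 8.58 ± 1.95 RPKM. The stress list had a camera adjusted p of 0.118, with adjusted p = 0.527 with an estimated correlation, and of 0.0119 with 2 decreases without control replicate 2. Both the clock and the stress list had medians of 0.02 with a camera direction of down, while fry called the clock list up with an adjusted p of 0.0157.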

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

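The scalings, the 3-library filter and the sample weights were chosen only after seeing the result. With 1 library left out, the genes called, dKO against control, ranged from 845 to 2224, from 755 to 1983 higher and from 90 to 241 lower. Without a filter 151 genes were lower. An adjusted p under 0.01 left 539 genes (490 higher, 49 lower) and 12 lists, and a minimum fold of 1.5 left 147 genes (139 higher, 8 lower). Median-ratio scaling gave 958 higher and 536 lower, upper-quartile scaling 953 and 540, and quantile normalization 1281 genes (727 and 554). Sample weights gave 4734 genes (4133 and 601), with weights of 5.33 for dKO replicate 1 and 0.311 for dKO replicate 3, and the cause was not tested. Of the list tests, camera with an estimated correlation called 0, and fry, which tests a list against no change and not against the other genes, called 12 in a direction, the circadian list (not called by camera) among them. Only the pericentral and female-biased lists were called down by fry (adjusted p = 0.0128 and 0.0454). All other lists that camera placed down did not pass the directional fry test, among them drug-metabolising cytochromes (0.105), lipogenesis (0.118), periportal (0.176) and hepatocyte genes (0.261). Those lists were low against the other genes, whose median log2 change was 0.23. In either direction, fry called the cytochrome, lipogenesis, periportal and hepatocyte lists (fry adjusted p = 0.00988, 0.0172, 0.00239 and 0.00187). The Stk3 log2 fold change was -0.44 under quantile normalization, and the Stk4 log2 fold change was -0.084 under median-ratio scaling, -0.077 under upper-quartile scaling and -0.16 under quantile normalization. The replicate block gave 1715 genes, and no sample correlated best with its own number (r of -0.081, -0.101 and -0.01). Of 98 named genes tested, 92 were called, 54 of them in every fit without 1 library and 65 under every scaling. Not run, as they need counts, were the planned RLE and upper-quartile factors, the CPM filter, voom and the negative binomial fits. At the estimated depth, genes under about 1 RPKM rest on few reads.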

Other observations

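Genes outside the fixed lists, and families that in part share members with those lists, were chosen here after their values were seen. Each gene given below with its levels kept its call in the 17 alternatives that keep the threshold, which leave out an adjusted p under 0.01 and a minimum fold of 1.5. Of other genes looked at, Anxa2, Clu, Mt2, Pon1, Uox and Hsd17b6 missed the threshold in 1 to 6 of these alternatives. The stability of those given thus reflects which genes are shown. No shared function was tested. Anxa5, which encodes annexin A5, rose from 19.8 ± 3.56 to 135 ± 35.1 RPKM. Mfge8, a bridging protein gene for engulfment, rose from 5.94 ± 1.42 to 48.1 ± 18.4 RPKM, and Gas6, a ligand gene of the TAM receptors, from 7.98 ± 1.67 to 44.6 ± 9.69 RPKM. The fatty acid and scavenger receptor gene Cd36 rose 5.67-fold to 79.5 ± 3.54 RPKM. Mt1, which encodes a metal-binding metallothionein, fell from 2059 ± 966 to 359 ± 83.6 RPKM. The related Mt2 missed the threshold in 6 of 17 alternatives (limma adjusted p of up to 0.122). Rnase4 fell from 539 ± 135 to 104 ± 37.4 RPKM, and reads of this ribonuclease gene can be shared with Ang, which lies at the same locus. The cytokine receptor gene Lifr fell from 82.3 ± 15.4 to 32.4 ± 3.62 RPKM, and Bcl6, a repressor gene, from 11.1 ± 1.78 to 3.83 ± 1.28 RPKM.

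Among 163 families grouped by symbol stem, 6 of 12 Sult genes fell and 0 rose (6 and 0 after median-ratio scaling). Of 67 Cyp genes, 18 fell and 4 rose (20 and 1 after scaling). Some of these Sult and Cyp genes were already counted in the lists above. Of 9 annexin genes, 5 rose and 0 fell (4 and 0 after scaling). With camera 8 families passed, all down, with adjusted p of 2.88e-15 for Cyp, 1.85e-10 for Sult, 4.12e-05 for Hsd, 0.000123 for Gbp, 0.00053 for Serpina, 0.00566 for Ces, 0.0259 for Psmb and 0.0263 for Ndufa. Annexin genes had an adjusted p of 0.0508. Each of these had adjusted p = 0.998 with an estimated correlation.

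All tests of this part except the splits were chosen only after seeing the result. Of 14 cholangiocyte and progenitor markers 13 were called higher in dKO, and the list had a camera adjusted p = 0.414 with an estimated correlation. The endothelial minus cholangiocyte median was -1.49 (95% bootstrap interval -2.16 to -1.18). That interval resampled genes and not libraries, so it does not measure the spread between samples. With 1 library left out, the endothelial median was 0.14 to 0.24 and the cholangiocyte median 1.44 to 1.95. The endothelial and cholangiocyte medians argue against a lower share of hepatocyte RNA that raises every other cell type alike. Only the endothelial list was compared in this way. Medians of the other cell lists were 0.64 for stellate and matrix genes and 0.56 for macrophage markers. They were 0.1 for lymphocyte and neutrophil markers and -0.56 for red blood cell genes. Scaling of RPKM to all reads is argued against by the 11 members called higher after median-ratio scaling. More cholangiocytes with unchanged expression per cell stays open. That explanation expects ratios between markers to stay level. Of 13 ratios to Krt19, 9 were higher in all dKO libraries, while 0 of 13 ratios to Epcam were higher and 11 were lower. Most of these markers thus rose by more than Krt19 and by less than Epcam, so the outcome depended on the reference. RNA of other cells in 1 marker lowers its own rise, so these ratios do not decide.

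Control replicate 3 stood above the other controls in genes higher in dKO, where for each control genes were picked that were called without it, with a dKO mean of at least 5 RPKM and at least 8 times the mean of the other 2 controls, a rule chosen after seeing the data. For control replicate 3 this gave 66 genes, its excess was above 0 at 65 of them, and the median was 8.2% of the dKO excess. The median was -3.4% for control replicate 1 over its own 42 genes and -3.4% for control replicate 2 over its own 46 genes. A chance deviation of 1 control library stays open, since genes regulated together deviate together and high values in 1 control lower the others in this measure. The spread of that fraction over genes was 1.48 times that between the other controls (interval 0.71 to 2.33). Mixing of dKO material into control replicate 3 at 1 fraction stays open as well. The spread was a median absolute deviation, which gives extreme genes little weight. The fraction had quartiles of 5.9% and 11.9% but ran from -0.1% for Omd and 1% for Mup20 to 30.2% for Cyp8b1 and 35.7% for Tpm3. Mixing at 1 fraction was not tested at such single genes.

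Of 14 female-biased genes 6 were called lower in dKO, 2 without control replicate 3 and 3 without control replicate 1 or dKO replicate 3, and the list had a camera adjusted p = 0.321 with an estimated correlation. Male animals among the dKO samples are argued against by Y-linked genes of at most 0.00897 RPKM in dKO libraries. The female-biased minus hepatocyte median was -1.45 (interval -2.08 to -0.31, again over genes and not libraries). With 1 library left out, the female-biased median was -2.08 to -1.51 and the hepatocyte median -0.3 to -0.16. These medians argue against a general loss of hepatocyte transcripts. The fall of pericentral hepatocyte genes stays open, since 0 of the 6 called female-biased genes are on that short list.

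As a check of grouping by chance, 1 of the 10 splits of the libraries into 3 and 3, the real one, gave as many called genes as the 2205 found, and the highest other split gave 0. Genes with an unadjusted p under 0.05 numbered 4190 in the real split and at most 820 in another. With 10 splits a share under 0.05 cannot be reached.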
